A study of Homo sapiens with 9 samples.

How the data were processed

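Total RNA was extracted from pancreatic cancer cells, AsPC-1 per the labels, with a Nucleospin RNA kit, and 100 ng were labelled with biotin by the WT Plus protocol for 1-colour whole-transcript arrays. The groups were cells with the blank plasmid (control) and cells with either of 2 shRNA plasmids against SLP-2 (sh1 and sh2), each expanded from a single colony after 3 weeks with Geneticin, with 3 arrays per group. Nothing in the sources says whether the arrays of a group came from separate cultures. The deposited table holds values that were read as log2 signals from their range (2.03 to 18.57), their 2 decimals and the near-identical distributions of the arrays. The authors summarised and normalized them across arrays with Transcriptome Analysis Console, whose version and settings are not given in the sources used here. The values were used as deposited, without further scaling. Detection calls are not given in the sources used here, so the lower quartile of the row means (4.21) served as a proxy for signals near the background.

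The table holds 21448 rows, of which 17709 carry 1 gene symbol and 3739 do not. Where a gene had more than 1 row (22 genes), the row with the highest mean stood for it in the gene lists, which left 17687 genes. Differences between groups were tested with limma 3.58.1 in R 4.3.3, with 1 linear model over the 9 arrays and a moderated t test for sh1 minus control, sh2 minus control and sh2 minus sh1. P-values were adjusted by the method of Benjamini and Hochberg over all rows of a comparison, and a row was called at an adjusted p under 0.05. Errors are standard errors from the model (SE) or standard deviations (SD) over 3 arrays. Numbers in the array names were not used as pairs, since deviations of arrays with the same number correlated across rows at -0.0358 to 0.180 and 2 of 9 pairs were over 0.1. Both of those pairs were of arrays numbered 1 (0.180 for control and sh2, 0.122 for sh1 and sh2). A block by number was fitted as an alternative.

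For 39 gene lists with 1036 members, of which 923 were measured, camera of limma compared each list with all other genes at a preset inter-gene correlation of 0.01, and p-values were adjusted over the 39 lists. The same test with a correlation estimated from the data, and counts of members with p-values adjusted over the list alone, are given beside it. The overlap of the lines was set against 100 simulations of unchanged groups that shared the controls. Gene order came from the RefSeq annotation of GRCh38, and a running median over 40 neighbouring genes with a signal above the median was compared with 1000 shuffles of the order for the correlation of neighbours and 20 for the largest running median. A run was at least 40 genes long with a running median beyond 0.4 in size.

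Genes named in the text followed a rule. They are STOML2, the measured hexosamine genes, the 10 genes up and the 10 down with the largest smaller change among those called in both lines, and the 5 up and the 5 down with the largest change in each comparison. From each list described, up to 4 members were named, by the same ranking among called members. The groups, comparisons, lists, naming rule and the alternatives for scaling, filter, prior, samples, block, threshold, correlation, rows per gene and leaving out each array were fixed before the data were examined. The use of gene order, the neighbour correction and the removal of regional runs were chosen after seeing the data.

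The pipeline was tested on simulated data with 200 changed rows among 21448. At a log2 change of 0.5, 11.7% of the changed rows were recovered in sh1 and 10.1% in sh2, at 1 it was 87.2% and 88.6%, and at 2 it was 100% and 99.9%, with 5.5% and 5.2% false calls. Only 200 rows were changed in these simulations, while 18.8% of rows were called in sh1 and 16.3% in sh2 in the data. The adjusted p threshold is stricter when fewer rows change, so the recovered shares do not give the recovery in the data. A list shifted by 0.5 was found in 20 of 20 simulations, with 0 other lists called. The simulated genes varied independently of one another, so these simulations cannot show how the list test behaves when genes are correlated.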

Results

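Gene expression was measured in cells that the labels name AsPC-1, an established human pancreatic adenocarcinoma cell line, after knockdown of STOML2. STOML2 encodes stomatin-like protein 2 (SLP-2), a protein of the mitochondrial inner membrane. One group carried the empty plasmid (control) and the other groups carried plasmids for a short hairpin RNA (shRNA) against STOML2 (sh1 and sh2). Each group had 3 arrays, and each was grown from 1 single colony picked after 3 weeks of selection with Geneticin. The 9 arrays gave a log2 signal for 21448 rows, of which 17709 carried 1 gene symbol. Array medians lay between 6.57 and 6.65, and 4.21 was the lower quartile of the row means. Signals correlated at r = 0.994 to 0.996 across rows between arrays of a group and at 0.982 to 0.988 between groups. The number of arrays limits the precision, and because a group is 1 clone, p-values measure only the spread between arrays of a clone, which may be technical.

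STOML2, the target of both shRNAs, was strongly reduced in both lines. Its log2 signal was 13.67 ± 0.03 (SD, n = 3) in the control, 8.32 ± 0.12 (SD, n = 3) in sh1 and 7.73 ± 0.34 (SD, n = 3) in sh2. The change against the control was -5.35 ± 0.16 (SE) in sh1 (limma, adjusted p = 2.31e-09) and -5.94 ± 0.16 (SE) in sh2 (adjusted p = 1.63e-09). STOML2 was lower in sh2 than in sh1, by a difference of -0.59 on the log2 scale (adjusted p = 0.0394), a call that was lost when any 1 array other than sh2 array 2 was left out (-0.66 to -0.40, adjusted p = 0.0548 to 0.113). The 40 nearest expressed neighbours of STOML2 on chromosome 9, from DNAJA1 to TOMM5, had a median change of -0.51 in sh1 and -0.46 in sh2, and 36 of the 40 were lower in each line. STOML2 was the 1 of 4 measured stomatin family genes that passed in either line (1 also adjusted over the list alone, camera adjusted p = 0.219 in sh1 and 0.292 in sh2).

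**Figure D1:**
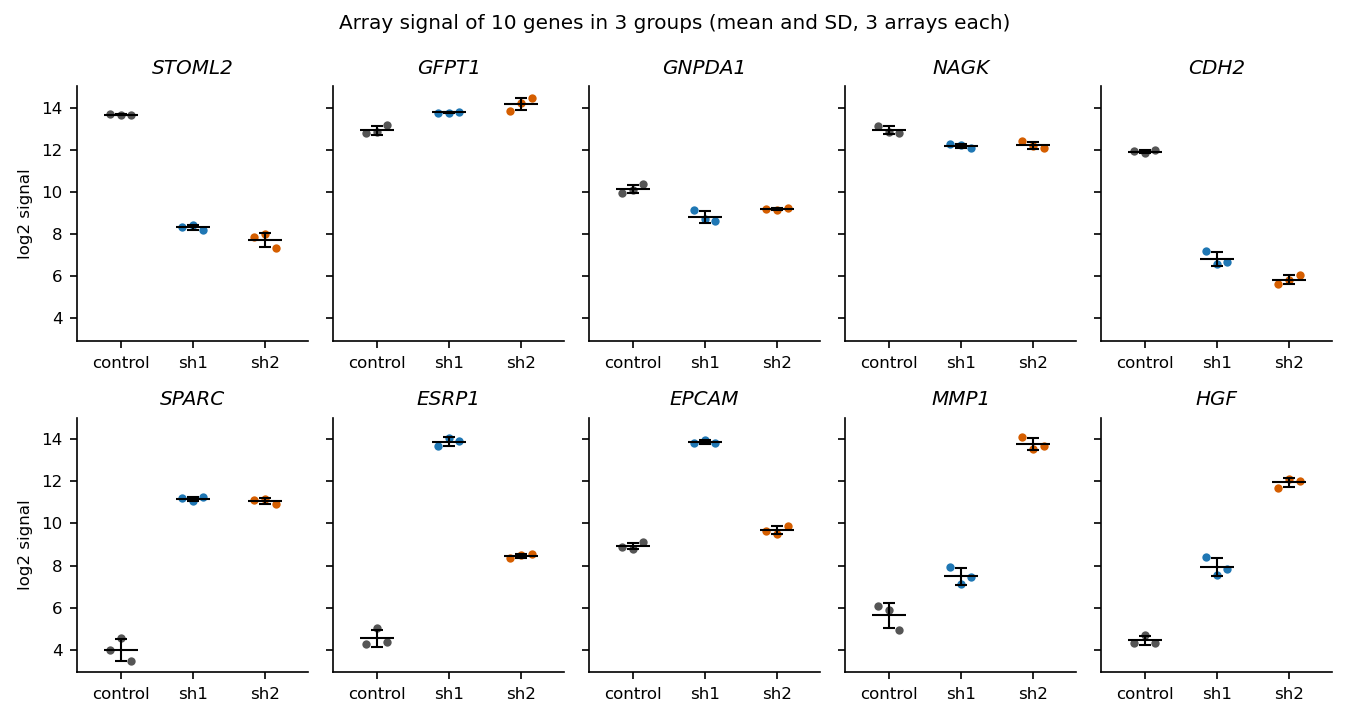
Log2 array signal (y axis) of 10 genes in the control, sh1 and sh2 groups (x axis); each point is 1 array, and bars give the mean and SD of 3 arrays. STOML2 fell from 13.67 to 8.32 and 7.73, GFPT1 rose from 12.94 to 13.78 and 14.19, and ESRP1 and EPCAM were highest in sh1 while MMP1 and HGF were highest in sh2.

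The study's title names the enzyme that limits the rate of hexosamine biosynthesis, the route from fructose 6-phosphate to UDP-N-acetylglucosamine. GFPT1, which encodes an enzyme of that rate-limiting step, rose in both lines. Its signal was 12.94 ± 0.21 (SD, n = 3) in the control, and its change was 0.84 ± 0.17 (SE) in sh1 (limma, adjusted p = 0.00395) and 1.25 ± 0.17 in sh2 (adjusted p = 0.000329). GNPDA1, whose enzyme turns glucosamine 6-phosphate back into fructose 6-phosphate, fell by 1.32 in sh1 and by 0.95 in sh2 (adjusted p = 0.000159 and 0.00192). NAGK, the kinase that salvages N-acetylglucosamine, fell by 0.75 and by 0.72 (adjusted p = 0.0031 and 0.00462). GNPNAT1, the acetyltransferase of the pathway, rose by 0.55 in sh1 (adjusted p = 0.015), while its difference in sh2 was 0.21 (adjusted p = 0.376). None of the other measured members on the list passed in either line. UAP1, the last enzyme of the pathway, differed by -0.23 in sh1 and -0.09 in sh2 (adjusted p = 0.293 and 0.72). OGT, which attaches O-linked N-acetylglucosamine, differed by 0.19 and 0.39 (adjusted p = 0.504 and 0.143), and OGA, which removes it, by -0.02 and -0.57 (adjusted p = 0.966 and 0.0921). GNPDA2 differed by -0.37 and -0.34, AMDHD2 by 0.09 and -0.13, and UAP1L1 by 0.28 and -0.23. Of the 10 measured members, 2 rose and 2 fell in sh1 (2 and 3 adjusted over the list alone). In sh2, 1 rose and 2 fell (1 and 4 adjusted over the list alone). The list did not shift as a whole (camera adjusted p = 0.767 in sh1 and 0.427 in sh2, and its median and test differed in sign in sh1). GFPT2, the paralog of GFPT1, and PGM3, another member of the list, had no row with 1 gene symbol and were not analysed here. The values above therefore say nothing about GFPT2. GNPDA1 lies on chromosome 5 among neighbours that were lower in both lines, and after neighbour correction its change was -0.93 in sh1 (adjusted p = 0.00188) and -0.36 in sh2 (adjusted p = 0.185), which no longer passed.

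The comparison of both shRNA lines with the control asks which genes moved with STOML2 whichever shRNA was used. Both lines gained SPARC, a secreted matrix glycoprotein, and lost EDIL3, a secreted integrin-binding protein, and CDH2 (N-cadherin). SPARC rose from 4.0 ± 0.53 (SD, n = 3) in the control, under the lower quartile of the rows, to 11.17 ± 0.10 in sh1 and 11.06 ± 0.13 in sh2. EDIL3 fell by 6.86 on the log2 scale in sh1 and by 8.63 in sh2, and CDH2 fell by 5.11 and 6.08. With a preset correlation between genes, the lists of cholesterol synthesis and TGF-beta target genes passed as lower in both lines, and those of MAPK feedback and ATF4 target genes as higher. None of these calls held with an estimated correlation (adjusted p = 0.0982 and 0.0914 for cholesterol, 0.489 and 0.432 for TGF-beta, 0.489 and 0.367 for MAPK, and 0.489 and 0.493 for ATF4, in sh1 and sh2). In total 4025 rows passed in sh1 (2094 higher and 1931 lower) and 3498 in sh2 (1787 higher and 1711 lower). Of these, 1916 changed in the same direction in both lines (919 higher and 997 lower) and 115 in opposite directions. At a change of at least 2-fold, 1200 rows passed in sh1 (544 higher and 656 lower), 966 in sh2 (436 higher and 530 lower) and 478 in both in the same direction (184 higher and 294 lower).

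Among the genes that rose in both lines, the most marked after SPARC, ranked by the smaller of both changes, were SCIN, an actin-severing protein, and TNIK, a kinase of Wnt signalling. SCIN rose by 5.15 in sh1 and 5.66 in sh2, and TNIK by 4.30 and 6.75. ESRP1, an epithelial splicing regulator, rose by 9.34 and 3.93. GJA1, a gap junction protein, rose by 3.79 and 3.82, and KCNH7, a potassium channel, by 4.92 and 3.69. HGF, the ligand of the receptor MET, rose by 3.50 and 7.51. F2RL2, a protease-activated receptor, rose by 3.36 and 5.0, SCG2, a secretogranin, by 3.43 and 3.33, and MAL2, a protein of apical transport, by 3.29 and 9.80. Among the genes that fell in both, PLPP4, a phospholipid phosphatase, changed by -6.44 and -6.29. The adhesion molecules CADM1 and ALCAM changed by -6.44 and -6.16, and by -4.10 and -4.54. DPYSL3, a cytoskeletal regulator, changed by -4.63 and -4.33, and NRP2, a semaphorin receptor, by -3.95 and -4.38. The dopamine receptor DRD1 changed by -4.50 and -3.74, and the interferon-inducible GTPase GBP2 by -4.16 and -3.66. Adjusted p-values of these genes, with SPARC, EDIL3 and CDH2, were at most 6.77e-07 (HGF in sh1, limma), and all 3 arrays of each line lay on the same side of the control arrays. SPARC, SCIN, SCG2 and MAL2 lay under the lower quartile in the control, as did PLPP4 in sh1 and DPYSL3 and NRP2 in both lines, so those changes may be limited by the background, and DRD1 and SPARC lie in the chromosome 5 run of sh2.

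**Figure D2:**
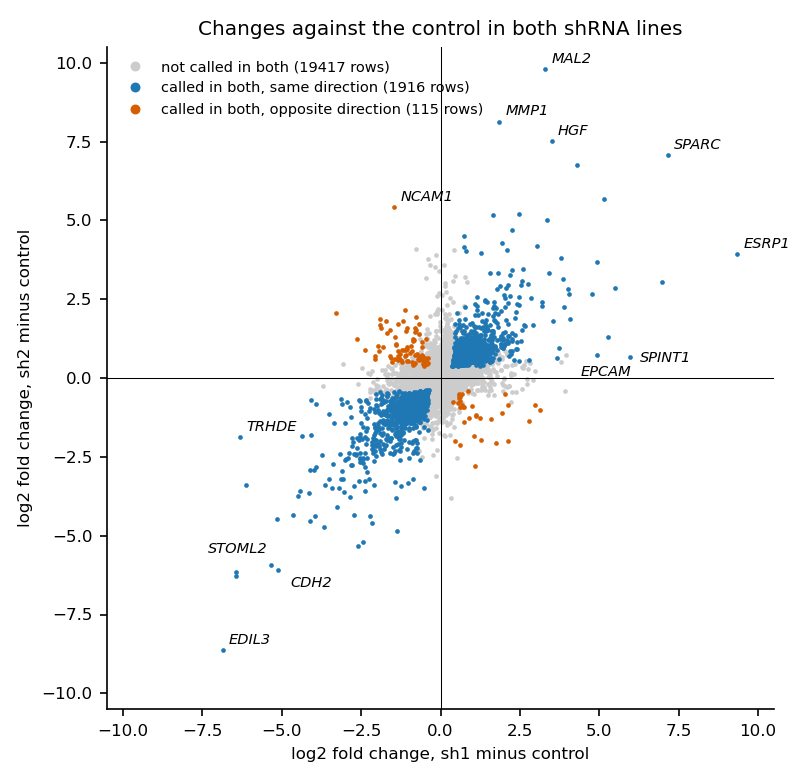
Log2 fold change against the control in sh1 (x axis) and sh2 (y axis), 1 point for each of 21448 rows. Blue points are the 1916 rows called in both lines in the same direction, orange points the 115 called in opposite directions, and grey points the rest; SPARC lies at 7.16 and 7.06, and EDIL3 at -6.86 and -8.63.

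Many cholesterol biosynthesis and uptake genes fell. Of 20 measured members, 11 fell in sh1 and 13 in sh2, with 8 in both and 0 that rose in either (median -0.54 and -0.65). When adjusted over the list alone, 15 fell in sh1 and 18 in sh2, where 1 rose. In camera the adjusted p was 2.75e-06 and 6.81e-10, and the adjusted p = 0.0982 and 0.0914 with an estimated correlation. CYP51A1, the lanosterol demethylase, changed by -1.25 in sh1 and -1.72 in sh2, and ACAT2 by -0.77 and -1.96. HMGCS1, which makes the precursor of mevalonate, changed by -0.64 and -1.40, and DHCR7, the last enzyme of the pathway, by -0.77 and -1.08. Among fatty acid synthesis and desaturation genes, 2 of 21 rose and 6 fell in sh1, and 3 rose and 8 fell in sh2. Adjusted over the list alone, 4 rose and 9 fell in sh1, and 3 and 8 in sh2. For the list as a whole, the camera adjusted p was 0.0275 and 0.0218, and the adjusted p = 0.223 and 0.367 with an estimated correlation. ACSL5, an acyl-CoA synthetase, changed by -2.93 and -2.52, and the desaturase FADS2 by -1.29 and -1.83. The elongase ELOVL5 changed by -1.0 and -0.93 but lies in the chromosome 6 runs of lower genes in both lines, and after neighbour correction it was -0.45 and -0.46 (adjusted p = 0.0272 and 0.0282). The elongase ELOVL7 rose by 3.72 and 0.96. The fatty acid call was lost in both lines when control array 1 was left out (camera adjusted p = 0.0939 and 0.0600), and in sh2 without rows under the lower quartile (0.050).

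Among feedback targets of the MAPK pathway, more members rose than fell. Of 24 measured members, 11 rose and 3 fell in sh1, 15 rose and 1 fell in sh2, and 10 rose in both (median 0.36 and 0.99). When adjusted over the list alone, 12 rose and 4 fell in sh1, and 15 and 3 in sh2. The camera adjusted p was 0.00697 and 4.34e-07, and the adjusted p = 0.489 and 0.367 with an estimated correlation. EREG, a ligand of the EGF receptor, rose by 3.04 in sh1 and 4.19 in sh2. SPRY1, an inhibitor of receptor signalling, rose by 2.85 and 2.55, and DUSP6, an ERK phosphatase, by 1.68 and 2.27, while the ephrin receptor EPHA4 changed by -2.79 and -1.89. Without members inside regional runs the sh1 call was lost (camera adjusted p = 0.0502).

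A minority of ATF4 and amino acid stress targets passed, and nearly all of those rose. Of 29 members, 13 rose and 1 fell in sh1, 12 rose and 1 fell in sh2, and 9 rose in both (median 0.49 and 0.60). Adjusted over the list alone, 17 rose and 2 fell in sh1, and 13 and 1 in sh2. In camera the adjusted p was 9.93e-05 and 0.00025, and the adjusted p = 0.489 and 0.493 with an estimated correlation. Without sh1 array 2 the sh1 median was 0.32. GDF15, a secreted stress cytokine, rose by 3.54 and 1.80, and the pseudokinase TRIB3 by 1.51 and 1.02. SLC7A11, a cystine transporter, rose by 1.21 and 1.15, and SHMT2, a mitochondrial serine hydroxymethyltransferase, by 0.89 and 1.04.

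A minority of TGF-beta targets fell. In sh1, 1 of 21 members rose and 7 fell, in sh2, 2 rose and 8 fell, and 5 fell in both (median -0.31 and -0.39). Without sh1 array 2 the sh1 median was -0.46 (camera adjusted p = 0.000118). When adjusted over the list alone, 2 rose and 8 fell in sh1, and 2 and 10 in sh2. For the list as a whole, the camera adjusted p was 0.000643 and 0.000125, and the adjusted p = 0.489 and 0.432 with an estimated correlation. COL1A1, a fibrillar collagen, changed by -3.19 and -3.48, PMEPA1, an inhibitor of TGF-beta signalling, by -2.52 and -2.53, and the matrix proteins TGFBI and LTBP2 by -2.45 and -2.58, and by -4.08 and -1.81. Mesenchymal genes and regulators of epithelial-mesenchymal transition, a list that shares TGFBI with the TGF-beta targets, had more members that fell than rose. In sh1, 2 of 23 rose and 11 fell (median -0.61), and in sh2 3 rose and 9 fell (median -0.17). Without regional runs the mesenchymal median was -0.46 in sh1 and -0.27 in sh2 (camera adjusted p = 3.35e-05 and 0.00253), and without control array 1 it was -0.12 in sh2 (0.0279). Adjusted over the list alone, 2 rose and 13 fell in sh1, and 4 and 10 in sh2. The camera adjusted p was 2.20e-05 and 0.0131, and the adjusted p = 0.0982 and 0.367 with an estimated correlation. CDH2 led the fall, SNAI2, a transcription factor of the transition, changed by -2.79 and -2.76, and the collagen gene COL5A1 by -2.74 and -3.42, whereas SPARC rose. VIM (vimentin) differed by -0.76 in sh1 (adjusted p = 0.000895) and -0.05 in sh2 (adjusted p = 0.858), and after neighbour correction its sh1 value was 0.36.

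A minority of nuclear-encoded genes of the respiratory chain passed, and most of those fell. Of 32 complex I genes, 2 rose and 7 fell in sh1, and 0 rose and 6 fell in sh2 (median -0.20 and -0.17). When adjusted over the list alone, 2 rose and 8 fell in sh1, and 1 and 6 in sh2. In camera the adjusted p was 0.0307 and 0.020, and the adjusted p = 0.442 and 0.367 with an estimated correlation. NDUFB6 changed by -0.65 and -0.65, NDUFA2 by -0.60 and -0.94, NDUFA11 by -0.76 and -0.59, and NDUFB7 by -0.57 and -0.87. Of 35 genes of complexes II to V, 1 rose and 9 fell in sh1, and 0 rose and 9 fell in sh2 (median -0.26 and -0.22). Adjusted over the list alone, 1 rose and 13 fell in sh1, and 0 and 12 in sh2. For the list as a whole, the camera adjusted p was 0.00096 and 0.00118, and the adjusted p = 0.489 and 0.493 with an estimated correlation. Without control array 1 the sh1 median of complexes II to V was -0.16 (camera adjusted p = 0.00633). UQCRQ changed by -0.78 and -1.12, UQCR11 by -0.95 and -0.77, and COX7B by -0.59 and -0.57. NDUFA2 and, in sh2, UQCRQ lie among neighbours on chromosome 5 that were lower as well, and neighbour correction ended their calls there. It left NDUFA2 at -0.21 in sh1 and -0.29 in sh2 (adjusted p = 0.554 and 0.39), and UQCRQ at -0.50 in sh2 (adjusted p = 0.068). After neighbour correction the complex I median in sh2 was -0.26 (camera adjusted p = 0.00565). The complex I call was lost in both lines without control array 1 (camera adjusted p = 0.0939 and 0.0618), in sh1 without sh1 array 3, without rows under the lower quartile and without regional runs (0.0569, 0.0508 and 0.0502), and in sh2 without sh2 array 3 (0.0535).

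Changes in sh1 and sh2 correlated at r = 0.639 across rows, and 71.0% of rows had the same sign. Unchanged groups simulated against the same controls gave r = 0.501 on average and 66.7% of rows with the same sign. The covariance was 0.189 against a simulated 0.0158, a difference of 0.174, and noise shared through the controls adds the same covariance to both. For the counts of shared calls no such separation was made. Independent lists of these sizes would share 174 higher and 154 lower rows, against 919 and 997 found, but that expectation leaves out the shared controls. Simulated unchanged groups shared 0 rows, which decides nothing, since they gave almost no calls (0.05 in sh1 on average). The 3 control arrays cannot be split with at least 2 in each part, so part of the excess in these counts may come from the shared controls.

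The comparison of sh1 alone with the control was marked by a gain of epithelial genes. ESRP1 rose from 4.55 ± 0.40 (SD, n = 3) to 13.89 ± 0.20, and the desmosomal plaque protein PKP2 from 5.22 ± 0.53 to 12.19 ± 0.06. EPCAM, an epithelial adhesion molecule, rose by 4.94 (limma, adjusted p = 1.77e-09), and ST14, the membrane protease matriptase, by 3.79 (adjusted p = 2.13e-07). Of 30 genes of epithelial junctions and keratins, 17 rose and 3 fell (21 and 3 adjusted over the list alone), with a median of 0.85. This shift passed with the preset and with an estimated correlation (camera adjusted p = 1.25e-08 and 0.0148). DSC2, a desmosomal cadherin, went the other way (-2.43).

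SPINT1, an inhibitor of matriptase, rose by 5.96 in sh1 and 0.66 in sh2, and CKMT1B, a mitochondrial creatine kinase, by 5.50 and 2.86. CKMT1B has a nearly identical copy, CKMT1A, so its value is uncertain. Both SPINT1 and CKMT1B lie on chromosome 15, whose expressed genes were higher in sh1 as a whole. TRHDE, which degrades thyrotropin-releasing hormone, fell by 6.30 in sh1, to a level under the lower quartile, and by 1.88 in sh2 (adjusted p = 6.73e-05). SLCO1B3, an organic anion transporter, fell by 6.13 and by 3.40 (adjusted p = 4.60e-08 in sh2). TRHDE and SLCO1B3 were thus lower in both lines, more so in sh1. SPINT1 passed in sh2 (adjusted p = 0.0273) but not without control array 1, control array 2, sh2 array 1 or sh2 array 2. Integrins in sh1 had 1 of 18 that rose and 9 that fell (1 and 9 adjusted over the list alone) and a median of -0.42. The camera adjusted p was 0.00644, and the adjusted p = 0.223 with an estimated correlation. ITGB8 changed by -2.22, ITGA3 by -1.64, ITGB1 by -1.23 and ITGA10 by -0.96. ITGB1 lies in a run of lower genes on chromosome 10, where neighbour correction left it at -0.32 (adjusted p = 0.126) and ended its call. Without such runs the integrin list had a median of -0.16 and its call was lost (camera adjusted p = 0.0547). The median was -0.27 after neighbour correction and -0.88 without rows under the lower quartile (0.0125 and 0.00177).

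The list of CEACAM and other surface adhesion glycoproteins passed as lower in sh1, with 0 of 18 that rose and 6 that fell (1 and 6 adjusted over the list alone). Its median was only -0.06 (-0.13 to -0.01 with 1 array left out), beside a mean of -0.69, so a few members carried the shift. In camera the adjusted p was 0.0102, and the adjusted p = 0.489 with an estimated correlation. The members that fell most were ALCAM, the sialomucin PODXL (-3.69), the tetraspanin CD82 (-2.15) and NCAM1 (-1.45), none of which is a CEACAM. A minority of mitosis genes passed, with 11 of 30 higher and 1 lower (12 and 2 adjusted over the list alone) and a median of 0.29. For the list as a whole, the camera adjusted p was 0.000998, and the adjusted p = 0.658 with an estimated correlation. CCNB2, a mitotic cyclin, rose by 1.31, the kinesin KIF23 by 1.26, the checkpoint kinase BUB1B by 0.91 and NUSAP1 by 0.87, and all of these lie on chromosome 15. After neighbour correction CCNB2 was 0.79 and KIF23 0.42 (adjusted p = 0.00875 and 0.0363), while the calls of BUB1B (0.19, adjusted p = 0.358) and NUSAP1 (0.10, adjusted p = 0.716) were lost. The list of replication-dependent histones passed as higher, with 7 of 40 that rose and 0 that fell (7 and 0 adjusted over the list alone) and a median of 0.37. The camera adjusted p was 2.20e-05, and the adjusted p = 0.663 with an estimated correlation. H1-3 rose by 1.14, H3C8 by 0.85, H4C1 by 0.66 and H4C13 by 0.61, and these genes belong to families of near-identical copies, so their values are uncertain.

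In the comparison of sh2 alone with the control, MAL2 rose from 3.47 ± 0.20 (SD, n = 3) to 13.27 ± 0.16, MMP1, an interstitial collagenase, from 5.64 ± 0.60 to 13.78 ± 0.29, and HGF from 4.44 ± 0.23 to 11.95 ± 0.22. Gains of that order were seen in sh1 too, with ESRP1 at 9.34 beside 9.80 for MAL2 in sh2. MMP1 rose by 8.14 in sh2 (limma, adjusted p = 1.07e-08) and by 1.86 in sh1 (adjusted p = 0.000854). The epithelial list did not pass in sh2, where 8 of 30 rose and 5 fell (camera adjusted p = 0.154), 9 and 5 adjusted over the list alone. All 8 also rose in sh1, 3 members fell in both lines, and 2 rose in sh1 but fell in sh2. ESRP1 and PKP2 rose there by 3.93 and 3.05, while DSC2 fell by 5.19 and the desmosomal cadherin DSG2 fell by 3.19. The mitochondrial ribosomal protein list passed as lower in sh2, with 4 of 43 that rose and 14 that fell (6 and 14 adjusted over the list alone) and a median of -0.17. In camera the adjusted p was 0.0128, and the adjusted p = 0.605 with an estimated correlation. MRPS23 changed by -1.09, MRPL14 by -0.97 and MRPL36 by -0.95, and MRPL14 and MRPL36 lie in runs of lower genes on chromosomes 6 and 5. Neighbour correction ended both calls and left MRPL14 at -0.21 (adjusted p = 0.503) and MRPL36 at -0.42 (adjusted p = 0.0866). The list call was lost without control array 1 (camera adjusted p = 0.0600), after neighbour correction (0.213) and without regional runs (0.105). In sh1, the mitochondrial ribosomal list had 5 that rose and 8 that fell (6 and 16 adjusted over the list alone, camera adjusted p = 0.13). Histone and mitosis genes did not pass as lists in sh2, and both results hang on single arrays. Of the histones 2 rose and 0 fell (0 and 0 adjusted over the list alone, median 0.18, camera adjusted p = 0.0801), and the list passed with the replicate block (0.0262) and without control array 1, sh2 array 2 or sh2 array 3 (0.0176, 0.0079 and 0.0193). Without sh2 array 1 the histone median was 0.0275 (0.741), without control array 3 it was 0.0983 (0.367), and after neighbour correction 0.0831 (0.251). Of the mitosis genes 6 rose and 2 fell (8 and 4 adjusted over the list alone, median 0.18, camera adjusted p = 0.154), and the list passed without sh2 array 2 (0.0294), after neighbour correction (0.00627) and without regional runs (0.0433). Without sh2 array 1 the mitosis median was 0.11 (0.356).

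**Figure D3:**
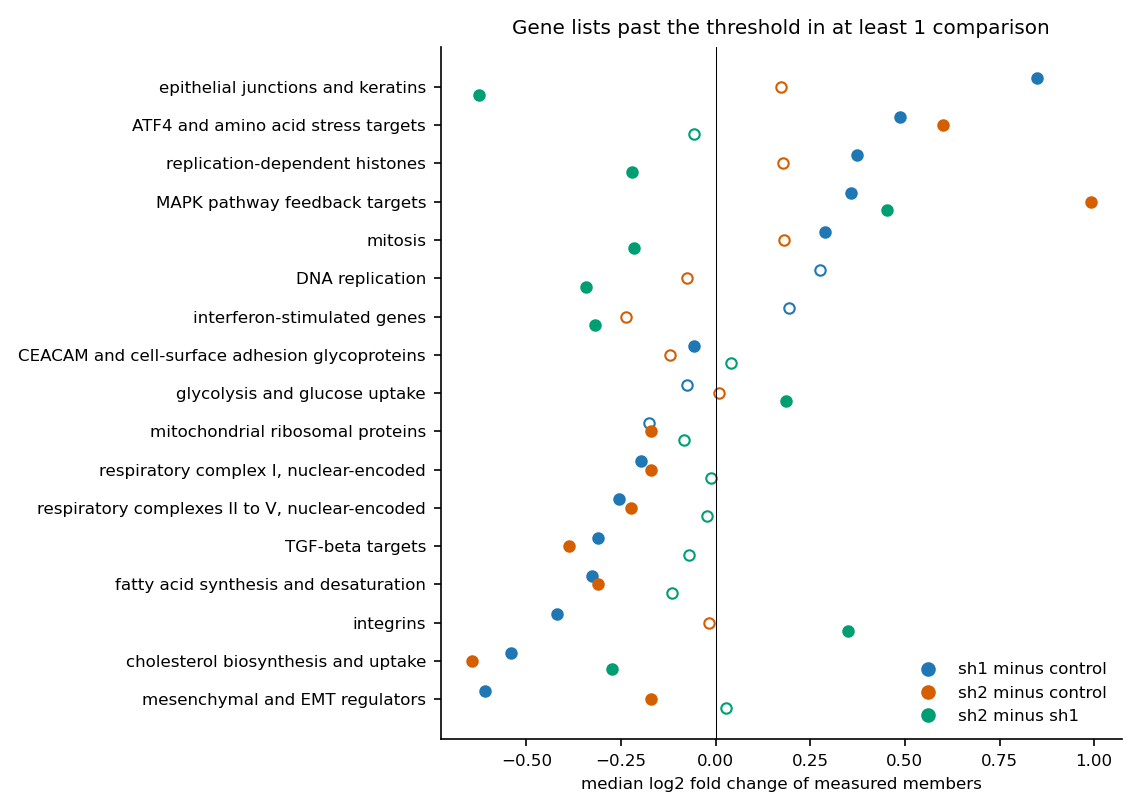
Median log2 fold change of the measured members (x axis) of the 17 gene lists (y axis) that passed in at least 1 comparison, for sh1 minus control, sh2 minus control and sh2 minus sh1. Filled points passed the camera test with the preset correlation and open points did not; the epithelial list lies at 0.85 in sh1 and 0.17 in sh2, and the cholesterol list at -0.54 and -0.65.

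The direct comparison of sh2 with sh1 asks how far 2 lines with the same target resemble one another. They differed in 2423 rows (1229 higher and 1194 lower in sh2), of which 755 differed by at least 2-fold (437 higher and 318 lower). NCAM1, a neural adhesion molecule, was 6.88 higher in sh2 (limma, adjusted p = 6.58e-10), MAL2 6.51 higher and MMP1 6.28 higher. ZNF385D, a zinc finger protein, was 5.36 higher and NID2, a basement membrane nidogen, 4.87 higher. On the other side, the differences of sh2 minus sh1 were -5.41 for ESRP1, -5.31 for SPINT1, -4.32 for the membrane protease TMPRSS2, -4.20 for EPCAM and -4.14 for GATM, an enzyme of creatine synthesis, where SPINT1 and GATM lie in the chromosome 15 run. Of the 1916 rows called in the same direction in both lines, 406 also differed between the lines.

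The epithelial list was lower in sh2 than in sh1, with 1 of 30 members higher and 15 lower (2 and 16 adjusted over the list alone) and a median of -0.62. This passed with the preset and with an estimated correlation (camera adjusted p = 5.15e-10 and 0.00988). The MAPK feedback list passed as higher in sh2, with 8 higher and 2 lower (14 and 2 adjusted over the list alone, camera adjusted p = 0.000104, adjusted p = 0.569 with an estimated correlation). ETV1, an ETS transcription factor, was 3.64 higher and SPRY2 2.23 higher. The integrin list passed as higher too, with 6 higher and 1 lower (9 and 1 adjusted over the list alone, camera adjusted p = 0.00374, adjusted p = 0.352 with an estimated correlation), among them ITGA2 (1.92) and ITGB8 (1.79). The integrin median was 0.35, 0.21 without regional runs, where the call was lost (0.0662), and 0.59 without rows under the lower quartile (0.000942). The list of glycolysis and glucose uptake passed as higher in sh2, with 4 of 21 higher and 0 lower (4 and 0 adjusted over the list alone, camera adjusted p = 0.00568, adjusted p = 0.841 with an estimated correlation). Among them were PDK1, which inhibits pyruvate dehydrogenase (1.11), the hexokinase HK2 (0.90) and PFKP (0.84), and PFKP lies in the chromosome 10 run and was -0.26 after neighbour correction. Against the control, 1 rose and 3 fell in sh1, and 5 rose and 0 fell in sh2 (1 and 4, and 5 and 0 adjusted over the list alone, camera adjusted p = 0.302 and 0.404).

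The DNA replication list passed as lower in sh2 than in sh1, with 1 of 37 higher and 7 lower (1 and 14 adjusted over the list alone, camera adjusted p = 0.000146, adjusted p = 0.841 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, differed by -0.97, CCNE1 (cyclin E) by -0.75 and the replicative helicase subunit MCM2 by -0.73. Against the control, 5 rose and 1 fell in sh1, and 4 rose and 6 fell in sh2 (9 and 1, and 4 and 8 adjusted over the list alone, camera adjusted p = 0.0516 and 0.301). The sh1 list lay close to the threshold, and as a higher list it passed with the 2 groups fitted alone (0.0366), without control array 3, sh1 array 2, sh2 array 2 or sh2 array 3 (0.0463, 0.00544, 0.0386 and 0.0422), after neighbour correction (0.011) and without regional runs (0.0158). It did not pass under the other settings, among them without sh1 array 1 (0.18) or sh1 array 3 (0.142) and with an estimated correlation (0.78). In sh2 the DNA replication list had a median of -0.08, passed as lower without sh2 array 1 (-0.12, 0.0495), and was -0.015 without sh2 array 2 (0.892) and -0.135 without control array 2 (0.224). The interferon-stimulated list passed as lower in sh2 than in sh1, with 2 of 38 higher and 12 lower (4 and 14 adjusted over the list alone, camera adjusted p = 0.00849, adjusted p = 0.569 with an estimated correlation). The antiviral GTPase MX1 differed by -2.41, the transcription factor IRF1 by -1.68 and IFI6 by -1.17. Against the control, 7 rose and 6 fell in sh1, and 5 rose and 11 fell in sh2 (12 and 7, and 9 and 14 adjusted over the list alone, camera adjusted p = 0.277 and 0.262). The cholesterol list also passed as lower, with 2 higher and 7 lower (2 and 7 adjusted over the list alone, camera adjusted p = 0.0218, adjusted p = 0.569 with an estimated correlation), and STARD4 differed by -1.40. For mitosis the list was lower, with 1 higher and 5 lower (1 and 7 adjusted over the list alone, camera adjusted p = 0.017, adjusted p = 0.841 with an estimated correlation). Histone genes were lower as a list (median -0.22), with 0 members past the test in either direction, also adjusted over the list alone (camera adjusted p = 0.00872, adjusted p = 0.841 with an estimated correlation). The mitosis call was lost when sh1 array 1, sh1 array 3 or sh2 array 2 was left out (camera adjusted p = 0.103, 0.113 and 0.198), and the histone call when sh1 array 1, sh1 array 2, sh2 array 2 or sh2 array 3 was left out (0.0794, 0.0814, 0.192 and 0.116). The cholesterol call was lost without sh1 array 1, sh1 array 3 or sh2 array 3 (0.0624, 0.0771 and 0.15), and the mitosis call without regional runs (0.263) and after neighbour correction (0.376).

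With all arrays and the values as deposited, the other lists did not pass the camera test in any comparison, and the smallest camera adjusted p among them against the control was 0.0835 (cytosolic ribosomal proteins in sh1). That list passed as lower in sh1 without control array 3 or sh1 array 1 (0.0463 and 0.0424), the NF-kB list without sh1 array 2 (0.0349), and the stomatin family after neighbour correction (0.0404). Matrix metalloproteinases and plasminogen activators moved both ways, with 4 of 24 higher and 3 lower in sh1 (4 and 3 adjusted over the list alone) and 5 higher and 3 lower in sh2 (9 and 4 adjusted over the list alone). Besides MMP1, MMP15 rose by 2.12 in sh1 and 1.71 in sh2 and SERPINE2 by 1.45 and 1.5, whereas MMP2, a gelatinase, changed by -1.97 and -1.42. Of p53 targets, 4 of 22 rose and 5 fell in sh1 (4 and 5 adjusted over the list alone), and 2 rose and 5 fell in sh2 (3 and 5 adjusted over the list alone). CDKN1A, a cyclin-dependent kinase inhibitor in the chromosome 6 run of sh2, changed by -1.35 and -2.09, and MDM2 by 0.89 and 1.03. N-glycan genes had 1 of 28 higher and 7 lower in sh1 (2 and 7 adjusted over the list alone), and 2 higher and 4 lower in sh2 (2 and 4 adjusted over the list alone). The mannosidase MAN1A1 changed by -2.10 and -3.40, and MGAT4B, a branching enzyme, by -1.10 and -1.17. Mucins and mucin-type O-glycosylation genes had 3 of 28 higher and 3 lower in sh1 (3 and 3 adjusted over the list alone), and 3 higher and 3 lower in sh2 (6 and 4 adjusted over the list alone). The mitochondrial scaffold, protease and cardiolipin list, which holds partners of SLP-2, had 1 of 27 higher and 4 lower in sh1 (1 and 5 adjusted over the list alone), and 1 higher and 3 lower in sh2 (1 and 3 adjusted over the list alone). FIS1, a mitochondrial fission protein, changed by -1.09 and -0.77, and MICOS13, a cristae junction protein, by -0.96 and -0.83. Of 27 NF-kB targets and cytokines, 0 rose and 5 fell in sh1 (3 and 6 adjusted over the list alone), and 3 rose and 5 fell in sh2 (4 and 6 adjusted over the list alone), with TRAF1 at -1.16 and -1.20.

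Hypoxia response genes had 5 of 24 higher and 6 lower in sh1 (5 and 8 adjusted over the list alone) and 5 higher and 6 lower in sh2 (6 and 6 adjusted over the list alone), and the glucose transporter SLC2A3 rose by 1.46 and 1.60. Heat shock and immediate stress genes had 2 of 24 higher and 5 lower in sh1 (4 and 7 adjusted over the list alone) and 2 higher and 5 lower in sh2 (3 and 6 adjusted over the list alone), and the chaperone HSPA1A changed by -1.12 and -0.94. The unfolded protein response had 2 of 24 higher and 2 lower in sh1 (2 and 1 adjusted over the list alone) and 4 higher and 3 lower in sh2 (6 and 4 adjusted over the list alone). Targets of YAP and TAZ had 5 of 21 higher and 1 lower in sh1 (6 and 1 adjusted over the list alone) and 3 higher and 5 lower in sh2 (3 and 5 adjusted over the list alone), with IGFBP3 at 2.07 and 2.86. WNT targets had 3 of 21 higher and 4 lower in sh1 (3 and 5 adjusted over the list alone) and 1 higher and 2 lower in sh2 (1 and 2 adjusted over the list alone). BCL2 family and death receptor genes had 4 of 27 higher and 4 lower in sh1 (4 and 4 adjusted over the list alone) and 5 higher and 3 lower in sh2 (6 and 3 adjusted over the list alone), with the survival factor BCL2L1 at -0.89 and -0.83. Gemcitabine transport and metabolism genes had 1 of 17 higher and 3 lower in sh1 (1 and 3 adjusted over the list alone) and 2 higher and 4 lower in sh2 (3 and 5 adjusted over the list alone), with the efflux pump ABCG2 at -0.94 and -0.94. Markers of the classical pancreatic cancer subtype had 1 of 23 higher and 1 lower in sh1 (1 and 1 adjusted over the list alone) and 2 higher and 0 lower in sh2 (2 and 0 adjusted over the list alone), with AGR2, a secretory disulfide isomerase, at 2.25 and 4.68. Basal-like markers had 3 of 21 higher and 1 lower in sh1 (3 and 3 adjusted over the list alone) and 2 higher and 1 lower in sh2 (2 and 1 adjusted over the list alone). Cytosolic ribosomal protein genes had 0 of 36 higher and 2 lower in sh1 (0 and 2 adjusted over the list alone) and 0 higher and 2 lower in sh2 (0 and 2 adjusted over the list alone).

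Markers of other cell types showed no shift as lists. Fibroblast and stellate cell markers had 3 of 16 higher and 3 lower in sh1 (3 and 3 adjusted over the list alone) and 1 higher and 3 lower in sh2 (1 and 3 adjusted over the list alone). Haematopoietic markers had 0 of 20 higher and 2 lower in sh1 (0 and 1 adjusted over the list alone), and 1 higher and 1 lower in sh2 (0 and 1 adjusted over the list alone). Endothelial markers had 0 of 15 past the test in sh1 and 1 that rose in sh2 (ENG), and acinar and islet markers had 0 of 17 past it in either line, with the same counts adjusted over the list alone. Median, mean and test differed in sign in sh1 for the lists of hexosamine, mucin, mitochondrial scaffold, unfolded protein, hypoxia, YAP and TAZ, basal-like, gemcitabine, heat shock and haematopoietic genes. They did so in sh2 for mucin, mitochondrial scaffold, stomatin, p53, hypoxia, and YAP and TAZ genes. Between sh2 and sh1 they did so for hexosamine, N-glycan, mucin, complex II to V, TGF-beta, basal-like, BCL2 family, gemcitabine and endothelial genes.

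Genes that neighbour one another on a chromosome moved together in both lines. In sh1 the 324 expressed genes of chromosome 15 had a median change of 0.76 and 92.6% of them were higher, while a run of 85 genes on chromosome 10 (TUBB8 to ZNF32) had a median of -0.98 and a run of 70 genes on chromosome 6 (C6orf89 to BMP5) a median of -0.69. In sh2 a run of 246 genes on chromosome 5 (GIN1 to TRIM41) had a median of -0.63 and a run of 79 genes on chromosome 6 (SRSF3 to RAB23) a median of -0.75. Part of this was shared by the lines. Chromosome 5 was lower in both (medians of -0.31 in sh1 and -0.53 in sh2, with 22.2% and 10.9% of expressed genes higher). So was chromosome 6 (-0.23 and -0.20, with 30.6% and 34.3% higher), where the named runs of sh1 and sh2 overlapped. Chromosome 15 was higher in sh2 too (0.25, with 75.3% higher), and chromosome 12 was higher in both (0.32 and 0.32, with 76.8% and 82.2% higher). Changes of adjacent expressed genes correlated across genes with Spearman's rho = 0.292 in sh1 and 0.283 in sh2, and in 1000 shuffles of the gene order, the highest was 0.0340 and 0.0406 (one-sided permutation p = 0.001 in each, the smallest these shuffles can give). Genes are not independent replicates, which this order shows. Runs held 6.09% of expressed genes in sh1 and 13.7% of the calls among them, and in sh2 6.72% and 15.2%. Of the genes named above, TGFBI, STARD4, IRF1 and MGAT4B lie in the chromosome 5 run of sh2, HSPA1A in another run of lower genes on chromosome 6 in sh2 (after neighbour correction -0.40, adjusted p = 0.342, its call lost), and SCIN, ETV1, AGR2 and ITGB8 in a run of higher genes on chromosome 7 in sh2. MDM2 and TRHDE lie in a run of higher genes on chromosome 12 in sh2 (TRHDE was -2.31 there after neighbour correction), and AMDHD2 in a run of higher genes on chromosome 16 in sh1.

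**Figure D4:**
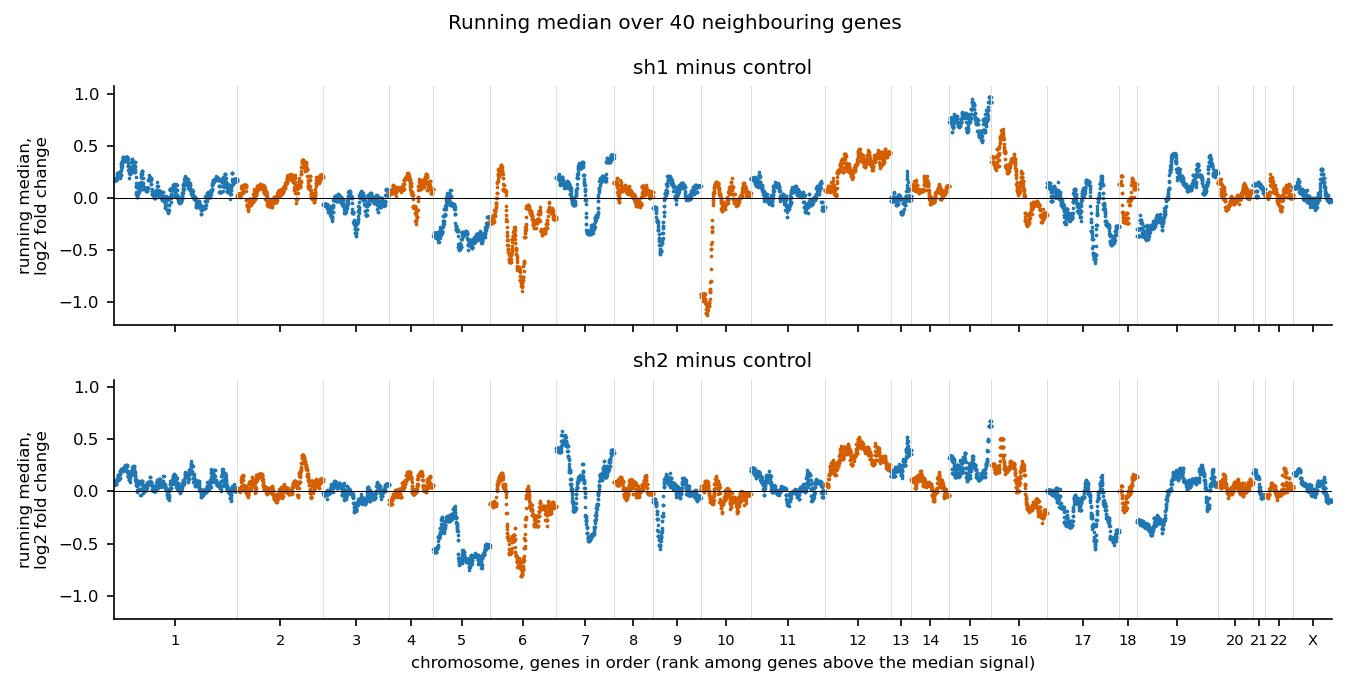
Running median of the log2 fold change over 40 neighbouring expressed genes (y axis), along the gene order of chromosomes 1 to 22 and X (x axis, rank among genes above the median signal), for sh1 and sh2 against the control. Colours alternate between chromosomes; chromosome 15 lies near 0.76 in sh1, and the long run on chromosome 5 near -0.63 in sh2.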

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

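The comparison of sh2 with sh1 was fixed beforehand, while the tests of explanations below and the counts over other splits were chosen after the results were seen. The values in this part stand out because lines with the same target differed in a direct test of sh2 against sh1. STOML2 differed by -0.59. Among genes that rose in both lines, the difference was 0.51 for SCIN, 2.46 for TNIK, -5.41 for ESRP1, -1.22 for KCNH7, 4.01 for HGF, 1.63 for F2RL2 and 6.51 for MAL2. Among genes that fell in both, it was -1.77 for EDIL3, -0.97 for CDH2, 0.76 for DRD1 and 0.50 for GBP2. For genes named by their change in 1 line, with the same sign in the other, it was -3.92 for PKP2, -5.31 for SPINT1, -2.64 for CKMT1B, 4.42 for TRHDE, 2.72 for SLCO1B3 and 6.28 for MMP1. It was 6.88 for NCAM1, 5.36 for ZNF385D, 4.87 for NID2, -4.32 for TMPRSS2, -4.20 for EPCAM and -4.14 for GATM. Median differences of lists were -0.62 for epithelial genes, 0.45 for MAPK feedback targets, 0.35 for integrins, 0.19 for glycolysis, -0.34 for DNA replication, -0.32 for interferon-stimulated genes, -0.28 for cholesterol genes, -0.21 for mitosis and -0.22 for histones. Leaving out 1 array moved some of these medians, to -0.18 for interferon-stimulated genes without sh1 array 2, -0.37 for histones without sh2 array 1, -0.125 for mitosis without sh2 array 2 and 0.305 for glycolysis without sh2 array 3.

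Runs of neighbouring genes shifted together against the control. The smaller of both lines' largest running medians was 0.815, above 0.392, the highest with the gene order shuffled, which argues against a chance order. Array scaling would move every chromosome alike, but beside 0.76 for chromosome 15 in sh1 (SD between arrays 0.03) the highest median of another chromosome was 0.32. Of the 324 expressed chromosome 15 genes (signal above the median), 92.6% were higher in sh1, against 52.5% of expressed genes elsewhere. The 194 dimmer genes of that stretch had a median of 0.105. A difference in copy number between the clones is a candidate explanation. It stays a hypothesis, since the chromosome was picked because it stood out and DNA was not analysed here.

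The epithelial list was higher in sh1 than in the control and in sh2. A deeper loss of STOML2 in sh1 is argued against by STOML2 itself, which differed by -0.59 (SE 0.16) between sh2 and sh1, although that call was lost without 1 array in 8 of 9 cases. Regional runs are argued against as the whole cause by a list median of 0.71 after neighbour correction, with the list still past the threshold. A difference between single clones that has nothing to do with STOML2 cannot be told apart from an effect of sh1, since each group is 1 colony and the lines differed in 2423 features. An effect of sh1 on targets other than STOML2 was not tested.

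Many features changed in the same direction in both lines. The covariance between the lines' changes was 0.189, beside a sampling variance of 0.0164 for the control mean. That argues against array noise of the shared controls as the whole source of the covariance, in which large changes weigh most. For the count of shared calls no such separation was made, so part of that count may come from the shared controls. Regional runs are argued against as the whole cause, since 1446 features were called in the same direction after neighbour correction and 1283 of the 1916 were kept. The control differed from both lines in the same direction in 1916 features, sh1 likewise from both other groups in 1237 and sh2 in 882. Chromosomes 5, 6, 12 and 15 moved in the same direction in both lines. Their medians over expressed genes were -0.31, -0.23, 0.32 and 0.76 in sh1, and -0.53, -0.20, 0.32 and 0.25 in sh2. The 40 nearest expressed neighbours of STOML2 on chromosome 9 were lower in both too (medians of -0.51 and -0.455). An effect of losing STOML2 therefore cannot be told apart from a control colony that stands apart for other reasons, since the control is 1 colony too.

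Splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real split gave 4025 features in sh1 (highest other 0), 1200 at 2-fold (0), 3498 in sh2 (0), 966 at 2-fold (0) and 2423 between the lines (0). It gave 13 lists in sh1 (highest other 11), 9 in sh2 (7) and 9 between the lines (6). In each of these cases 1 of 10 splits, the real one, reached the value. Other splits called 0 features yet passed up to 11, 7 and 6 lists, so list counts at the preset correlation say little about the grouping. Each other split mixes the groups and keeps part of their difference, so it cannot show how many lists would pass without one. For calls in the same direction in both lines, 1 of 100 splits of the 9 arrays reached 1916 (highest other 1174), which excludes chance at that share for the grouping of arrays. Arrays of a group come from 1 colony and resemble one another, so this shows that arrays cluster by colony, not that STOML2 is the cause. At 2-fold, 2 of 100 reached 478, and the highest other was 509. Both highest other splits kept the 3 control arrays together and mixed sh1 and sh2 arrays between the arms, so they follow the real difference from the control.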

How the results depend on the processing

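The neighbour correction and the removal of regional runs were chosen after the data were seen, and the other alternatives before. Leaving out each array in turn gave 3044 to 4047 features called in sh1, 2455 to 3587 in sh2, 1339 to 1744 in both in the same direction and 1803 to 2271 between the lines. At 2-fold the ranges were 1184 to 1265, 958 to 1055 and 459 to 508. STOML2 ranged from -5.40 to -5.28 in sh1 and from -6.07 to -5.75 in sh2. Its difference between sh2 and sh1 ranged from -0.72 to -0.40 (adjusted p = 0.0259 to 0.113) and passed only without sh2 array 2. With the 2 groups fitted alone it was -0.59 and no longer passed (adjusted p = 0.0852), and after neighbour correction it was -0.53 (adjusted p = 0.0524), where the cause was not tested.

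At an adjusted p under 0.01, by its construction a stricter bound, 2425 features were called in sh1, 1921 in sh2, 1029 in both and 1331 between the lines. With an estimated correlation 1 list passed in sh1, 0 in sh2 and 1 between the lines, the epithelial list in each case, and the cause was not tested. Leaving out arrays gave 11 to 15, 7 to 11 and 6 to 9 lists. With the replicate number as a block, 3996 features were called in sh1, 3432 in sh2, 1900 in both and 2364 between the lines, and 1771 of the 1916 shared calls were kept. Quantile normalization kept 1864 of them.

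After neighbour correction 3307, 2801, 1446 and 2151 features were called, and 1283 of the 1916 shared calls were kept. Without that correction, 1588 of the 1916 lay outside runs. A run needs at least 40 expressed genes and a running median beyond 0.4, so shorter or weaker regional shifts count as outside. The neighbours of STOML2 on chromosome 9 (medians of -0.51 and -0.455) were in no run. The 198 shared rows without 1 gene symbol were not placed in the gene order. Some genes were counted as reversed, since they changed direction when the correction subtracted their neighbours. In sh1 these were PFKP (0.28), VIM (0.36), COX5A (-0.10) and PDIA3 (-0.0909). In sh2 they were KIF20A (0.0506), SLC29A1 (0.0263) and MRPL2 (0.0461). Between the lines they were PFKP (-0.26), VIM (-0.45), PDIA3 (0.41) and NUSAP1 (0.00037). Changes of sign without a call were not all counted. AMDHD2, higher in sh1 without passing, was -0.33 after the correction (adjusted p = 0.108). The sh2 minus sh1 list calls for mitosis and histones ended as well (adjusted p = 0.376 and 0.0697). Over all alternatives, values of named genes kept their side of the threshold in 12331 cases, gained a call in 150, lost one in 591 and reversed in 11. A change of sign without a call, such as that of AMDHD2, counts among the 12331. Lists kept their side of the threshold in 2147 cases, gained a call in 19 and lost one in 57. Changes of sign in a list median without a call are counted in the 2147. Signals under the lower quartile limit the folds of genes such as SPARC and MAL2.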

Other observations

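The choice of these genes was made after their values were seen. Of the 115 features called in opposite directions, 33 were higher in sh1 and lower in sh2, and 82 were the reverse. ZNF385D was -3.29 in sh1 and 2.07 in sh2, ATRNL1 2.12 and -2.0, SYT9 -1.91 and 1.88, MYH10 1.75 and -2.05, and ELOVL6 -1.87 and 1.60. The labels name the cells AsPC-1, and the identity of the line was not tested here. Of the 3739 features that do not carry 1 gene symbol, 437 were called in sh1 and 404 in sh2, and 198 changed in the same direction in both. Features with more than 1 symbol were put in this group with those that had none.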
